A study of Mus musculus with 12 samples.

How the data were processed

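Gene expression was measured by RNA sequencing of total RNA from cultured mouse bone marrow monocytes in 12 samples, 4 groups of 3. Per the submitters' processing notes the reads were handled with bcl2fastq, HISAT2 2.2.1 and edgeR 3.3.3 on the GRCm38 build. The counting tool, annotation, strand setting and low-count filter are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical paralogs cannot be told apart.

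The authors deposited 3 tables that hold, per the file headers, values for 6 libraries each, a log2 fold change, a p-value and an adjusted p-value. The library columns are read as a signal, normalized counts per gene that the authors scaled to a common library size within a table; this comes from the values, since no header names the unit. The same library's values differ between tables by a factor of 0.882 to 1.13 that is nearly constant across genes (SD at most 0.00811), so tests stay within a table except for the interaction. Whole reads could not be recovered; values near 1 count had medians of 0.802 to 1.27 per library, and depth is unknown. Testing the files showed that each table lists only genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. The deposited p-values imply 15661, 15822 and 15541 genes tested for IFNβ at 12 h, time without IFNβ and time with IFNβ. Another deposited table gives a fold change for 5 genes at 24 h, read here as log2 from the values. Of 2038 gene identifiers 1947 matched a RefSeq symbol of the GRCm38 annotation and 71 a synonym only; coordinates are from that annotation.

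Groups and replicate numbers come from the sample labels, and every library column was mapped to a sample by name. The planned test for counts was not used, because the files hold normalized values of selected genes. The number of changed genes and their direction are therefore the authors' own calls, and limma 3.58.1 in R 4.3.3 was run on log2(value + 1) with a variance trend over the listed genes, with Benjamini-Hochberg adjustment over the implied number tested. The listed genes were selected for small p-values, which lowers their spread, so limma here describes those genes and is no independent test of them. The interaction was fitted over the 12 libraries for 224 genes and adjusted over those genes; the plan named values without a test for tables of fold changes alone, and the library values allowed this test. In simulated libraries with 200 changed genes, limma was adjusted over the genes of each table alone. It recovered 54.0% of 2-fold and 87.0% of 4-fold changes over the 1388 genes of the 12 h table. It recovered 51.0% and 80.0% over the 645 of time without IFNβ, and 55.0% and 94.0% over the 602 of time with IFNβ. The real fits of these tables were adjusted over the larger implied number tested. These rates therefore overstate what those fits could recover. For the interaction, with 60 changed genes among 224, limma recovered 13.3% and 83.3%. False calls numbered 13, 1, 6 and 2.

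Samples of the same replicate number deviated together from their group means in all 9 pairs (r across genes, which are not independent replicates, from 0.184 to 0.559). Different numbers ranged from -0.450 to 0.188, with a median of -0.136, so the ranges overlap slightly. The replicate number is taken to pair the samples, and fits with it as a block are given where they change a count. Replicates differed by more than counting noise (mean squared difference at least 39.1 times the counting variance).

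Before the data were examined, 22 gene lists were fixed, with tests of each list by a two-sided Fisher's exact test on members listed against the implied number tested, assuming every member was tested, and an exact binomial test of direction against the table's split. Values were adjusted over 66 tests of each kind. Both tests take genes as independent, whereas genes measured in the same libraries can change together, so these p-values may be too small. All listed members also passed when adjusted over the list alone, which their selection for small p-values largely fixes. Set tests that need all genes were not run. Named genes were chosen by a rule fixed in advance: among genes with adjusted p under 0.05 and non-overlapping replicates, outside the lowest 25% by abundance and leaving out unnamed predicted genes, the 8 largest in each direction, plus up to 4 members per list with the smallest p. Ifnb1, Ifnar1 and Ifnar2 were looked up in each table. Further symbols are given as members of a count. Alternatives were stricter thresholds, filters, a pseudocount of 0.1, the replicate block, each library left out, and, chosen after seeing the data, fits without a variance trend. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.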

Results

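RNA sequencing was done on monocytes purified from mouse bone marrow by magnetic sorting and kept in culture with 20 ng/mL M-CSF, the growth factor that drives monocytes toward macrophages. The cells received 100 U of interferon β (IFNβ), a type I interferon, or none, and RNA was taken after 12 h or 24 h. The 12 samples form 4 groups of 3 replicates: control at 12 h, IFNβ at 12 h, control at 24 h and IFNβ at 24 h. The values used are the authors' normalized counts per gene and library in 3 tables, each listing only genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. A gene outside a table is therefore not shown to be unchanged. Total depth per library is unknown, since the tables hold part of each library. In the text, levels are normalized counts (mean ± SD, n = 3), and log2 differences are on the log2(normalized count + 1) scale with the standard error from limma; this scale understates the change of genes with low counts. Nothing in the labels says that replicates came from separate animals, so p-values of single genes measure the spread between these samples, which may be technical. The p-values of gene lists measure no spread between samples. They take genes as independent and may be too small.

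The first comparison asks what IFNβ did to the cells within 12 h. Antiviral effector genes rose together: Ifit1, which encodes a protein that binds viral RNA (chromosome 19, 34640889 to 34650009 in GRCm38), went from 528 ± 52.1 to 54009.6 ± 6480.5, a log2 difference of 6.67 ± 0.16. Ifi44 went from 24.1 ± 12.8 to 8491 ± 580.2 (8.57 ± 0.36), Phf11b from 158 ± 7.46 to 18633 ± 2807 (6.86 ± 0.17) and the surface marker Ly6a from 375 ± 27.4 to 31344 ± 4916 (6.37 ± 0.16). In the authors' deposited table, 56 of the 60 members of the interferon-stimulated list were higher with IFNβ and 0 were lower. Mx1 and Mx2 were not listed. By RefSeq synonym Ifi209 and Ifi213 are in the authors' deposited table as Pyhin1 (log2 fold change 4.01) and Pydc4 (7.76), outside the 56. The share listed exceeded the 5.32 members that independence would give (Fisher's exact test, two-sided, adjusted p = 9.41e-53). All 56 also passed when adjusted over the list alone, which follows from the selection of the listed genes and adds no evidence. The direction differed from the table's split (exact binomial test, adjusted p = 1.84e-09), as it did for MHC class I (0.00826) and cytokines (0.0285) and for no other list at 12 h.

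Components of the interferon pathway itself rose too. Usp18, a negative regulator of the receptor, went from 546 ± 61.1 to 18369 ± 2049.6 (5.07 ± 0.16). The transcription factor genes Stat2 and Irf9, whose products act downstream of the receptor, differed by 3.46 ± 0.16 and 1.65 ± 0.16 on the log2 scale. Of the 18 members of the signalling list, 6 were higher and 1, Ifngr1, was lower in the authors' deposited table (adjusted p = 0.00218, Fisher's exact test against 1.60 by chance). Of these members 4 also belong to the interferon-stimulated list. Ifnb1 itself was listed, at 1.21 ± 2.10 to 13.7 ± 16.8, and did not pass limma (adjusted p = 0.135). Ifnar1 and Ifnar2, which encode the receptor, were not listed in any of the 3 tables.

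MHC class I genes rose, and several class II genes fell. Of 20 genes for MHC class I and its peptide loading, 19 were higher and 0 were lower in the authors' deposited table, against 1.77 expected (adjusted p = 5.45e-18, Fisher's exact test). H2-Q6, H2-T22, H2-Q4 and H2-Q7 rose by log2 differences of 3.82 ± 0.17, 3.12 ± 0.16, 2.92 ± 0.15 and 3.09 ± 0.17; their sequences are close to one another, so reads may be split between them. Of the class II genes, H2-Ab1 went from 16712 ± 2492 to 3270.2 ± 659 (-2.36 ± 0.19), H2-Aa from 14161 ± 1842 to 3077 ± 623 (-2.21 ± 0.18) and H2-Eb1 from 7915 ± 847 to 1731 ± 307 (-2.20 ± 0.17). Ciita, the master regulator of class II transcription, fell from 6354 ± 586 to 925 ± 194 (-2.79 ± 0.18). In the authors' deposited table, 6 of the 13 members of the class II list were lower, and the 2 that were higher were the co-stimulatory genes Cd86 and Cd40. Members of the list were called more often than independence would give (adjusted p = 2.64e-05), but the direction did not differ from that of the whole table (exact binomial test, adjusted p = 0.155).

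Chemokine and cytokine genes rose in 18 of 30 members and fell in 1, Ccl22 (authors' deposited table; adjusted p = 4.17e-12, Fisher's exact test). Cxcl10, which attracts T cells, went from 173 ± 73.5 to 33159 ± 8188 (7.63 ± 0.28; chromosome 5, 92346638 to 92348889), the death ligand Tnfsf10 from 68.2 ± 26.7 to 2754 ± 432 (5.38 ± 0.27), Il18 from 56.9 ± 10.4 to 1525 ± 347 (4.71 ± 0.25) and Ccl4 from 238 ± 30.3 to 3698 ± 801 (3.94 ± 0.20). Of 27 cell death genes 11 were higher and 0 lower in the authors' deposited table (adjusted p = 6.40e-05); they include the necroptosis effector Mlkl (2.76 ± 0.16) and the inflammatory caspases Casp4 (2.44 ± 0.16) and Casp1 (1.44 ± 0.16), but also the survival genes Bcl2l1, Bcl2a1a and Bcl2a1d. Of 21 pattern recognition genes 8 were higher and 0 lower (authors' deposited table; adjusted p = 0.00125), led by the RNA sensor Tlr3 (6.05 ± 0.32) and the DNA sensor Tlr9, from 1949 ± 423 to 18841 ± 4207 (3.27 ± 0.21). Of 22 immediate early and stress genes 9 were higher (authors' deposited table; adjusted p = 3.38e-04), among them Ddit3 (1.85 ± 0.16), Atf3 (1.70 ± 0.17), Dusp1 (1.61 ± 0.19) and Trib3 (1.49 ± 0.16).

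Macrophage and monocyte genes went both ways at 12 h. In the authors' deposited table, 5 of 31 macrophage genes were higher and 8 lower (adjusted p = 8.36e-06 for being called at all), and limma called 11 of the 13. The Fc receptor gene Fcgr1 rose from 1417 ± 204 to 34399 ± 5748 (4.60 ± 0.18), the efferocytosis receptor gene Axl from 1101 ± 495 to 24556 ± 7234 (4.53 ± 0.28) and the transcription factor Maf from 1216 ± 229 to 11114 ± 2809 (3.18 ± 0.21), while Apoe fell from 26852 ± 6293 to 6958 ± 1199 (-1.93 ± 0.21). Among 23 monocyte genes 4 were higher and 2 lower (authors' deposited table; adjusted p = 0.0375). Ly6c2, the classical monocyte surface marker, rose by 2.92 ± 0.18 and its close relative Ly6c1 by 3.50 ± 0.28, and Plac8 rose by 2.35 ± 0.21. Fn1, which encodes fibronectin, fell from 127719 ± 16329.7 to 4146 ± 966 (-4.96 ± 0.20; chromosome 1, 71585473 to 71653280). Of 14 dendritic cell markers 4 were lower and 1, Xcr1, was higher (from 14.1 ± 10.2 to 213 ± 53.5; authors' deposited table, adjusted p = 0.0191): Cd209a fell from 278 ± 21.6 to 9.31 ± 6.46 (-5.07 ± 0.54), Irf4 from 2153 ± 529 to 237 ± 70.3 (-3.19 ± 0.25) and Itgax from 625 ± 34.4 to 122 ± 20.8 (-2.36 ± 0.22).

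The naming rule ranked genes by the authors' log2 fold change, and the order differs on the log2 scale printed here. The largest rises by the naming rule, beyond Ifi44, were in Apol9a, Sct, Hap1, Apod, Sectm1a, Apol9b and Ifit1bl1. Apol9a, Sct and Hap1 were listed at 0 in the controls and at 351 ± 67.0, 162 ± 17.4 and 149 ± 28.6 with IFNβ, so no fold is given. Apod went from 0.302 ± 0.523 to 843 ± 118 and Sectm1a from 0.302 ± 0.523 to 317 ± 75.9, both from less than 1 count in the controls. Apol9b, a near copy of Apol9a, went from 2.81 ± 2.72 to 1847 ± 332, and Ifit1bl1, which shares sequence with other Ifit genes, from 65.6 ± 16.8 to 38418 ± 7610.3 (9.19 ± 0.22). By the same rule, beyond Fn1 and Cd209a, the largest falls were in Sema6d, from 837 ± 107 to 16.8 ± 12.9 (-6.04 ± 0.63), Retnla (-4.26 ± 0.88), Hpgd (-3.91 ± 0.42), Abca6 (-4.26 ± 0.58), Kcnq3 (-4.08 ± 0.42) and Cyp1b1 (-4.14 ± 0.43). Retnla varied between controls, at 133 ± 165.

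Other lists held few called genes at 12 h in the authors' deposited table. Both stromal markers called, Kdr and Cdh5, were higher, Kdr from 251 ± 4.53 to 21081 ± 6331 (6.34 ± 0.22). Of the osteoclast list Tnfrsf11a was higher and Acp5, Atp6v0d2 and Itgb3 were lower. Ccnd1 and Cdkn1a of 37 cell cycle genes, Gzma and Gzmb of 17 T and NK cell markers, Npc2 and Gla of 27 lysosomal genes and Pfkp of 23 glycolysis and hypoxia genes were higher. Of 27 sterol genes Ch25h was higher and Abca1 lower, and 1 of 11 erythroid markers and Blk of 14 B cell markers were lower. Neutrophil and mast cell markers had 0 called members. Blk did not pass limma. None of these lists passed the Fisher test at adjusted p under 0.05.

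In total 1388 genes were in the authors' deposited table, 892 higher and 496 lower with IFNβ. The replicates of the groups did not overlap for 1365 of them, which the selection of the listed genes largely fixes. Refitted with limma over the listed genes and adjusted over the 15661 genes that the deposited p-values imply were tested, 1209 passed.

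**Figure D1:**
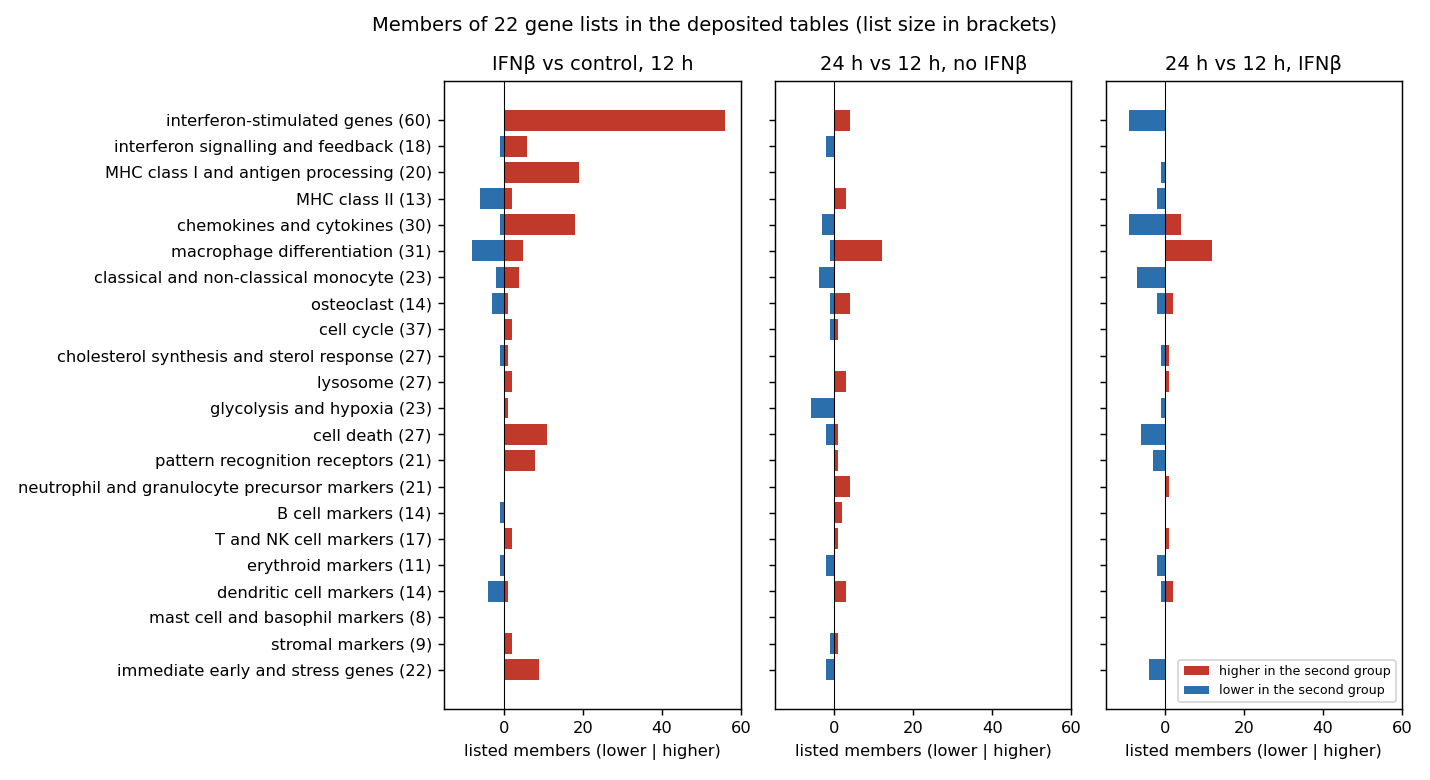
Number of members of each of the 22 gene lists in the authors' deposited table of each comparison, with members higher in the second group to the right of 0 and members lower to the left; list sizes are in brackets. With IFNβ at 12 h, 56 of 60 interferon-stimulated genes lie to the right, and with time under IFNβ 9 lie to the left.

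The second comparison asks how the control cells changed between 12 h and 24 h in M-CSF. Macrophage genes rose: C1qa, which encodes a complement subunit, went from 391 ± 237 to 3340.5 ± 1187 (3.19 ± 0.40; chromosome 4, 136895916 to 136898844), Gpnmb from 42282 ± 7783 to 176960.0 ± 22682 (2.07 ± 0.23), the fatty acid binding protein gene Fabp4 from 786 ± 295 to 3958 ± 937 (2.37 ± 0.29) and the lipase gene Lpl from 2344 ± 111 to 7126 ± 734 (1.60 ± 0.18). In the authors' deposited table, 12 of the 31 macrophage genes were higher at 24 h and 1, Arg1, was lower, against 1.26 expected (Fisher's exact test, adjusted p = 1.05e-09). The direction did not differ from the table's split (exact binomial test, adjusted p = 0.791), and limma called 9 of the 13, and 13 with the replicate number as a block. Monocyte genes fell in 4 of 23 members and rose in 0 (authors' deposited table; adjusted p = 0.0375; direction adjusted p = 0.0285, exact binomial test), with Fn1 from 142711 ± 17052 to 23366 ± 3139 (-2.61 ± 0.21), Vcan from 72892 ± 24572 to 24929 ± 7826 (-1.54 ± 0.30) and the transcription factor Klf4 at -1.15 ± 0.21.

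Of 14 osteoclast genes 4 were higher and 1, Car2, lower (authors' deposited table; adjusted p = 8.98e-04). The proton pump subunit gene Atp6v0d2 rose from 959 ± 501 to 6907 ± 2299.6 (2.92 ± 0.36) and the protease gene Ctsk by 1.42 ± 0.24. Of 23 glycolysis and hypoxia genes 6, Slc2a1, Slc16a3, Pdk1, Bnip3, Egln3 and Ankrd37, were lower and 0 higher in the authors' deposited table (adjusted p = 0.00125; direction, exact binomial test, adjusted p = 0.00565). In no other list of this comparison than these and the monocyte list did the direction differ from the table's split. With limma 0 of these 6 passed, and 1 passed with the replicate number as a block. Of 13 class II genes H2-Aa (1.11 ± 0.19), H2-Eb1 (1.02 ± 0.18) and H2-Ob were higher (authors' deposited table; adjusted p = 0.0391). Siglech, Ccr9 and Ccr7 of 14 dendritic cell markers were higher (adjusted p = 0.0445), Ccr7 from 476 ± 137 to 2012 ± 356 (2.11 ± 0.26). Retnlg, Mmp9, Stfa1 and Stfa2l1 of 21 neutrophil markers were higher (adjusted p = 0.0296); Mmp9 is also in the osteoclast list and the Stfa genes are near copies of one another. Ace, Car2, Dcstamp, Mmp9, H2-Ob, Siglech, Retnlg and Stfa1 did not pass limma without the block, and with it all but H2-Ob and Dcstamp did.

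By the naming rule, which leaves out genes of low abundance or with overlapping replicates, the largest rises in controls were in Prss46, listed at 0.331 ± 0.567 at 12 h and 71.1 ± 2.48 at 24 h, Tceal7, Bex1 (5.13 ± 0.55), the lipid phosphatase gene Plpp3, from 31.5 ± 4.39 to 950.1 ± 128 (4.87 ± 0.26), Fstl1 (4.34 ± 0.38), Npy (4.36 ± 0.50), Bhlhe41, from 141 ± 31.2 to 2498 ± 255 (4.16 ± 0.23), and Ptpn14 (4.14 ± 0.60). The largest falls by that rule were in Sh2d6 (-4.09 ± 0.66), Nfatc4 (-3.79 ± 0.52), Ccl24 (-3.97 ± 0.72), the stress pseudokinase gene Trib3, from 2589 ± 309.6 to 225 ± 60.9 (-3.54 ± 0.24), Car6 (-3.47 ± 0.65), Ehd2 (-2.96 ± 0.42), Nrbp2 and Itm2a (-2.69 ± 0.29). Nrbp2 did not pass limma without the block (-2.82 ± 0.64, adjusted p = 0.0713) and passed only with it.

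The remaining lists showed no excess in the authors' deposited table at adjusted p under 0.05. Ifi44, Iigp1, Ly6a and Lgals3bp of the interferon-stimulated list were higher, with Ly6a at 1.22 ± 0.23. Ccl22, Il1b and Il6 of the cytokine list, Socs1 and Cish of the signalling list, and Ier3 and Trib3 of the stress list were lower. Ctsb, Ctsd and Lipa of the lysosome list, Ms4a1 and Fcmr of the B cell list, Cd4 of the T cell list and Tlr3 of the pattern recognition list were higher. Slc4a1 and Ermap of the erythroid list were lower. Pairs with mixed directions were Ccnd1 (higher) and Cdkn1a (lower) of the cell cycle list, and Kdr (higher) and Col1a2 (lower) of the stromal list. Of the cell death list Casp12 was higher and Bcl2a1a and Ripk3 lower. Ifi44, Iigp1, Il1b, Il6, Socs1, Ier3, Lipa, Tlr3, Bcl2a1a, Slc4a1, Ermap, Col1a2, Casp12, Ms4a1, Fcmr and Cd4 did not pass limma without the replicate block. With it all but Casp12, Ms4a1, Fcmr and Cd4 did. MHC class I, sterol and mast cell lists had 0 called members.

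The authors' deposited table held 645 genes, 493 higher and 152 lower at 24 h, with 611 whose replicates did not overlap. With limma 277 passed, 473 with the replicate number as a block, and 49 with that block when no variance trend was fitted, so the count rests on how the spread is estimated. Leaving out 1 library gave between 67 and 228, each library left out lowering it.

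The third comparison follows the cells under IFNβ from 12 h to 24 h. Macrophage genes rose here as well: C1qa went from 158 ± 82.9 to 1749 ± 217 (3.58 ± 0.32), C1qb from 1828 ± 728 to 13239 ± 822 (2.93 ± 0.25), C1qc from 599 ± 334 to 6537 ± 452 (3.59 ± 0.32) and the efferocytosis receptor gene Mertk from 106 ± 50.5 to 962 ± 162 (3.26 ± 0.32). In the authors' deposited table, 12 of 31 macrophage genes were higher and 0 lower (Fisher's exact test, adjusted p = 8.09e-09, and for direction, exact binomial test, adjusted p = 0.0239). Limma called 11 of the 12, and Arg1 did not pass (adjusted p = 0.437). Monocyte genes fell in 7 of 23 members and rose in 0 in the authors' deposited table, and limma called 6 of the 7. Fisher's exact test gave adjusted p = 1.19e-04, and the exact binomial test of direction 0.0285. They include Fn1 (-2.54 ± 0.28), Klf4 (-1.70 ± 0.22), Ace (-2.22 ± 0.30) and Vcan (-1.80 ± 0.35).

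Of 60 interferon-stimulated genes 9 fell and 0 rose in the authors' deposited table (adjusted p = 0.00201; direction adjusted p = 0.0110), the guanylate binding protein genes among them: Gbp5 went from 6589.9 ± 438 to 2037 ± 357 (-1.71 ± 0.19), Gbp2 from 28938 ± 3838 to 9422 ± 843 (-1.61 ± 0.18) and the antiviral gene Rsad2 from 99132 ± 14505 to 40282 ± 3474 (-1.29 ± 0.20). The other 51 were not listed. Cytokine genes split, with 4 higher and 9 lower of 30 (authors' deposited table, Fisher's exact test, adjusted p = 4.19e-10), and limma called 12 of the 13. Cxcl10 fell, with a log2 difference of -2.73 ± 0.21, and the interleukin-1 antagonist gene Il1rn from 9523 ± 1067 to 2100.1 ± 369.9 (-2.19 ± 0.19), while the monocyte attractants Ccl7, Ccl12 and Ccl8 rose by 3.12 ± 0.28, 2.31 ± 0.20 and 5.36 ± 0.84. Of 27 cell death genes 6 fell and 0 rose (authors' deposited table; adjusted p = 0.00201; direction adjusted p = 0.0558), among them the survival genes Bcl2a1a (-2.52 ± 0.30), Bcl2a1d (-1.75 ± 0.20) and Bcl2a1b (-1.38 ± 0.20), whose reads may be shared, and Casp4 (-1.24 ± 0.18).

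Of 14 osteoclast genes Ctsk and Atp6v0d2 were higher and Ocstamp and Car2 lower (authors' deposited table; adjusted p = 0.00600). Of 22 stress genes Trib3, from 5801 ± 719.8 to 697 ± 89.7 (-3.06 ± 0.19), Ddit3 (-1.06 ± 0.18), Hspa1a and Hspa1b were lower (adjusted p = 0.0296); the last pair are near copies, and neither passed limma without the block. Of 14 dendritic cell markers Ccr7 and Ccr9 were higher and Xcr1 lower (adjusted p = 0.0404). Apart from the macrophage, monocyte and interferon-stimulated lists, the direction did not differ from the table's split in any list here. The co-stimulatory genes Cd86 (-1.86 ± 0.20) and Cd40 (-1.23 ± 0.18) fell. Further called genes, in lists that did not pass the Fisher test, were Abca1 and Ctsl (higher), Ch25h, Pfkp, Tapbpl, Tlr2, Clec4e, Clec4n, Slc4a1 and Ermap (lower), and Stfa2l1 and Cd4 (higher). Ccr7, Ccr9, Ocstamp, Ermap and Stfa2l1 did not pass limma without the block. Signalling, cell cycle, B cell, mast cell and stromal lists had 0 called members in the authors' deposited table.

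By the naming rule, the largest rises under IFNβ were in Gas6, a ligand of Axl and Mertk, at 793 ± 92.4 by 24 h (5.88 ± 0.31), the folate receptor gene Folr2 (4.74 ± 0.45), Ccl8, Pdgfc (4.58 ± 0.69), Prss46 (4.19 ± 0.68), Fam198b (3.73 ± 0.41), C1qa and C1qc. The largest falls by the same rule were in Col4a1 (-3.33 ± 0.43), Art3 (-3.35 ± 0.51), Sh2d6 (-3.10 ± 0.29), Slc4a11 (-3.27 ± 0.43), Trib3, Pla1a (-2.73 ± 0.42), Cxcl10 and Nes (-2.57 ± 0.46). Ifnb1 was listed here at low counts and did not pass limma (adjusted p = 0.717).

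The authors' deposited table held 602 genes, 335 higher and 267 lower at 24 h, with 591 whose replicates did not overlap. With limma 366 passed. The replicate block gave 570, but in that fit the prior degrees of freedom were infinite, so each gene's own spread did not count; without a variance trend the block gave 81. Leaving out 1 library gave between 148 and 314, each library left out lowering it.

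**Figure D2:**
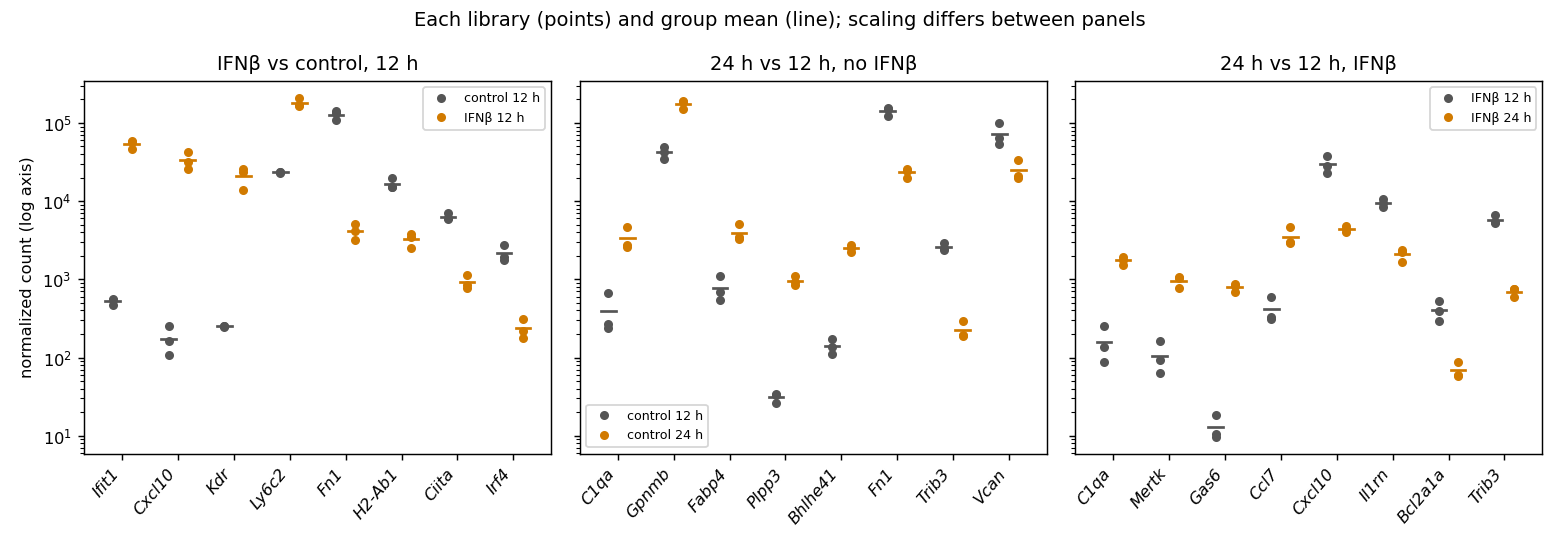
Normalized counts (log axis) of selected genes in each library (points) and their group means (lines), for IFNβ against control at 12 h, 24 h against 12 h without IFNβ, and 24 h against 12 h with IFNβ; the tables are scaled separately, so levels compare within a panel. Fn1 falls from 127719 ± 16329.7 to 4146 ± 966 with IFNβ at 12 h.

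To ask whether IFNβ altered the change with time, the 224 genes in both time tables were fitted together with limma over the 12 libraries. Another 799 of the 1023 genes in either table were listed in 1 arm only and could not be fitted. The counts below therefore do not measure how many changes with time IFNβ altered. The difference of the changes passed for 18 genes, 5 higher and 13 lower under IFNβ. Gas6 rose further with IFNβ (difference 2.19 ± 0.52), as did Rnase4 (1.63 ± 0.34) and the metalloprotease inhibitor gene Timp2 (0.92 ± 0.26). At 12 h IFNβ had lowered Gas6 (-2.87) and Timp2 (-1.57), and Rnase4 was not listed. The 24 h effect was formed without a test, as the 12 h effect plus the change with time under IFNβ minus that without it. It came to -0.69 for Gas6 and -0.65 for Timp2. The larger rise thus started from a lower level. Plpp3 (-1.77 ± 0.38), Cd200 (-1.84 ± 0.41), Gprc5b (-1.92 ± 0.39), Stra6l (-2.40 ± 0.29) and Gbgt1 (-2.42 ± 0.60) rose less. Of these, Cd200 (1.25), Gprc5b (2.45) and Stra6l (3.18) were already higher with IFNβ at 12 h, and Plpp3 and Gbgt1 were not listed there. Aplnr, the apelin receptor gene, changed by 1.17 without IFNβ and -2.02 with it, Ifit1bl1 by 1.46 without IFNβ and -1.29 with it, and the nuclear receptor gene Nr4a2 by 1.13 without IFNβ and -1.12 with it. Aplnr (4.36) and Ifit1bl1 (9.19) were higher with IFNβ at 12 h, and Nr4a2 was not listed there. With the replicate number as a block 45 genes passed, 17 higher and 28 lower. Both tables were scaled separately, which shifts a difference of changes by nothing as long as 1 scale applies within a table.

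**Figure D3:**
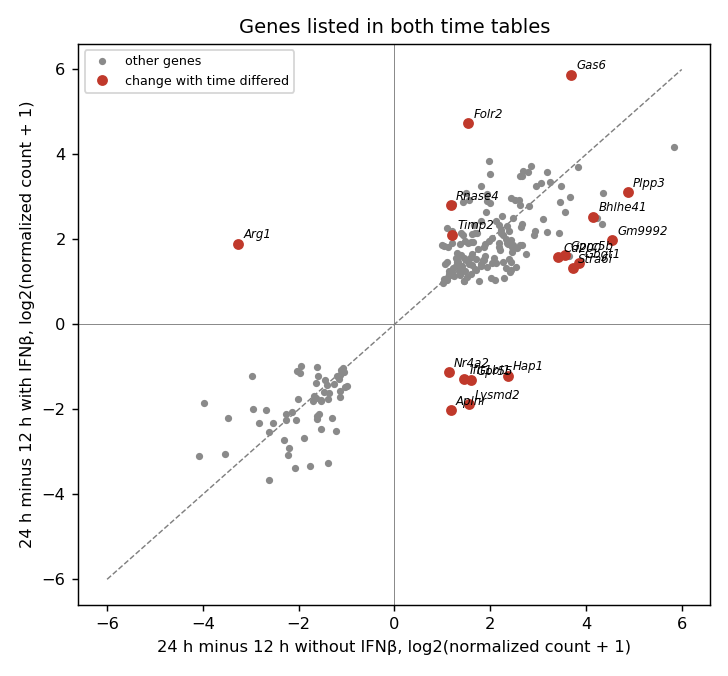
Change from 12 h to 24 h without IFNβ (x axis) and with IFNβ (y axis), both on the log2(normalized count + 1) scale, for the 224 genes in both time tables; the dashed line marks equal change and red points mark the 18 genes whose changes differed. Most genes lie in the quadrants of equal sign, and 7 do not.

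The lists of the 2 time tables overlapped in 224 genes. In the authors' deposited tables, 160 were higher and 57 lower at 24 h in both arms, where independent lists would share 10.6 and 2.61; 7 had opposite signs. No library is shared by these tables. The 12 h effect of IFNβ and the change with time under IFNβ shared 253 genes. Of the 164 that were higher with IFNβ at 12 h, 134 fell with time, and of the 89 that were lower, 70 rose, where independent lists would give 15.3 and 10.7 (authors' deposited tables). Across genes, which are not independent replicates, the log2 differences had a covariance of -2.69. These tables share the IFNβ 12 h libraries: unchanged simulated groups gave a covariance of -0.0770 with these genes' spreads. Pearson's r was -0.53 against -0.50 in the simulated groups, so r carries no evidence here. The 12 h effect and the change with time in controls shared 198 genes, 100 higher and 28 lower in both, against 28.1 and 4.81 for independent lists. Opposite signs were in excess too: 49 were lower with IFNβ and rose with time, against 15.6, and 21 were higher and fell, against 8.66. Their covariance was 1.18 against 0.0944 simulated, with r = 0.22 against 0.49 simulated. Noise of the shared controls made up 8.14% of that covariance (upper bootstrap bound over genes 21.96%). With 3 libraries the shared group could not be split, so part of either excess may come from the shared libraries. Selection of the listed genes enlarges these covariances and lowers the simulated spreads, so the gap between them does not exclude this.

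**Figure D4:**
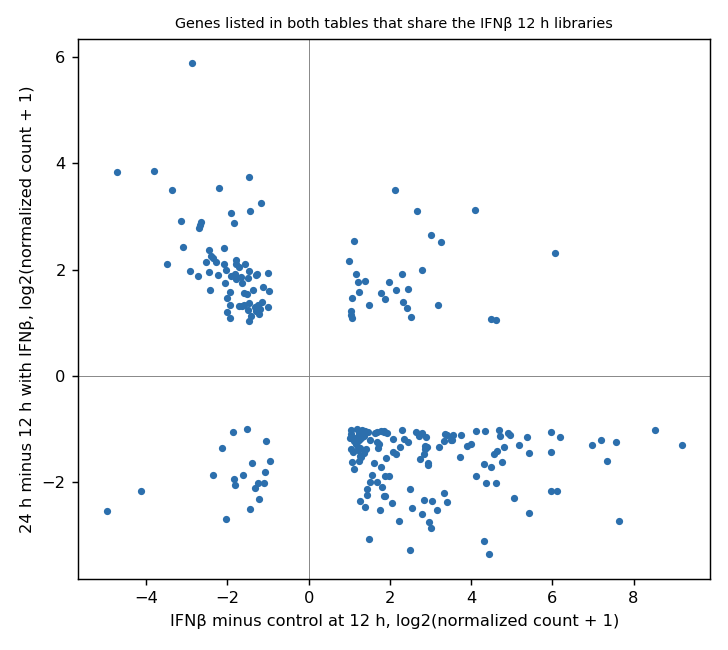
IFNβ effect at 12 h (x axis) and change from 12 h to 24 h under IFNβ (y axis), both on the log2(normalized count + 1) scale, for the 253 genes in both of these tables. Of these, 134 lie higher then lower and 70 lower then higher; the empty bands around 0 come from the minimum fold change of the tables.

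For IFNβ against control at 24 h, the authors' deposited table holds 5 genes with a single value each and no p-value or library values, so nothing was tested. The values were 5.74 for Ifit2, 5.74 for Irf7, 5.57 for Isg15, 4.28 for Il10 and 3.01 for Il6. The column is headed as a fold change with no scale; read as log2, all 5 lie where the other 3 deposited tables allow, and read as linear 4 of 5 do not. The rest of this comparison was not analysed here. For the 78 genes in all 3 tables, the 24 h effect can be formed from the other comparisons. It is the 12 h effect plus the change with time under IFNβ minus the change with time without IFNβ. It kept the 12 h sign in 69 genes, in 47 of them with a size of at least 1, and was smaller in size in 53. The 2 genes that changed sign with a size of at least 1 were Arg1 (2.93) and Lysmd2 (-1.57). For Arg1 none of the 3 changes used passed limma (adjusted p = 0.242, 0.161 and 0.437). Its controls at 12 h varied widely, at 7583 ± 8183. Fn1 came to -4.89, Ifit1bl1 to 6.44, Fabp4 to -2.39, Mmp12 to -2.37 and Mertk to 0.27. These sums run across tables that were scaled separately and carry no test.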

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

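The counts over other splits of the samples were chosen after the calls had been seen. For 18 of 224 genes the change from 12 h to 24 h differed between cells with and without IFNβ by limma's interaction test, and the named ones are listed as with minus without IFNβ (log2, ± SE). Genes whose change, not level, was higher under IFNβ were Gas6 (2.19 ± 0.52), Timp2 (0.92 ± 0.26), Rnase4 (1.63 ± 0.34) and Folr2 (3.19 ± 0.69). The IFNβ effect on Gas6 was -2.87 at 12 h and, formed from the 12 h effect and both changes with time, -0.69 at 24 h. On Timp2 it was -1.57 and -0.65. The change was lower for Plpp3 (-1.77 ± 0.38), Bhlhe41 (-1.62 ± 0.39), Aplnr (-3.19 ± 0.38), Stra6l (-2.40 ± 0.29), Ifit1bl1 (-2.75 ± 0.38), Gprc5b (-1.92 ± 0.39), Cd200 (-1.84 ± 0.41), Gbgt1 (-2.42 ± 0.60) and Nr4a2 (-2.25 ± 0.46). Arg1 also passed (5.16 ± 1.32), with controls at 12 h at 8557 ± 9281 normalized counts; limma's adjusted p was 0.0223, and 4.03e-06 with the replicate block.

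Of 100 splits of the time labels within each arm, the real one included, 11 called at least the real 18 genes and the highest other called 137, so by this count chance is not excluded. The other 10 were splits in which the 24 h label lay mostly on 24 h libraries in one arm and on 12 h libraries in the other, a structure that turns the shared change with time into a difference. Of the 99 other splits 52 had this structure, and among those without it the highest called 1. Those without it mix 12 h and 24 h libraries in at least 1 arm, which puts the change with time into the spread. All genes fitted had been listed for that change in both arms. The low counts there were therefore largely fixed in advance and do not argue against chance. Changes taken within replicate numbers, 3 pairs against 3, called 37 genes, and the highest other of 10 splits called 1. These genes had been selected for small p-values within each arm, which lowers their spread and favours the real split. Of 10 splits 1, the real one, was as large, and 10 splits are too few for a share under 0.05. The same holds for limma on IFNβ at 12 h (1 of 10 splits; 1209 genes, highest other 0), time without IFNβ (1 of 10; 277, highest other 0) and time with IFNβ (1 of 10; 366, highest other 0). In these 3, the genes had been selected for differing under the real labels, which fixes that the real split calls most, so these counts say nothing for or against chance.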

How the results depend on the processing

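The limma fit itself, the fits without a variance trend and those of the interaction without each library or with a pseudocount of 0.1, and the overlaps of limma's calls, were chosen after seeing the data. Against 1388, 645 and 602 genes in the authors' deposited tables, a log2 minimum of 2 left 604, 232 and 202; the cause is the stricter limit. For time without IFNβ limma called 277, a pseudocount of 0.1 gave 225, the replicate block 473, no variance trend 148, and the block without it 49; without one library 67 to 228 passed. For time with IFNβ limma called 366, with a pseudocount of 0.1 it was 313, with the replicate block 570, without a variance trend 139, and with the block but no trend 81; without one library 148 to 314. At 12 h limma with the replicate block called 1230, without one library 983 to 1125. A mean of at least 1 removed no gene, so its 277 and 366 say nothing. The interaction count went from 18 to 45 with the replicate block and 34 with it but no trend, and ranged from 14 to 23 without one library; the cause was not tested. Of 61 genes whose changes with time differed by at least 1, 35 were in all 3 tables; counting unlisted genes as 0 gave 860, by construction. Overlaps at a log2 minimum of 2 were 26 of 128, 44 of 204 and 67 of 217, and with limma's calls 58 and 106 for the first and last; the cause was not tested. List members at a log2 minimum of 2 numbered, for IFNβ at 12 h, 11 in MHC class I, 6 in macrophage, 4 in signalling and MHC class II, 3 in pattern recognition, 2 in cell death, 1 in osteoclast, cell cycle, sterol, stress, 0 in lysosome, hypoxia, B cell, erythroid; for time without IFNβ, 7 in macrophage, 2 in osteoclast and hypoxia, 1 in monocyte, neutrophil, erythroid, dendritic, stromal, stress, 0 in interferon-stimulated, signalling, MHC class II, cytokine, cell cycle, lysosome, cell death, pattern recognition, B cell, T and NK; for time with IFNβ, 7 in cytokine, 5 in macrophage, 2 in monocyte, 1 in osteoclast, sterol, cell death, stress, 0 in interferon-stimulated, MHC class I, MHC class II, lysosome, hypoxia, pattern recognition, neutrophil, dendritic. At adjusted p under 0.01 they were 0 in B cell and erythroid for IFNβ at 12 h, 3 in hypoxia, 1 in stromal, 0 in B cell for time without IFNβ and 1 in erythroid with it. Synonyms gave 1 in MHC class I and mast cell without and 2 in neutrophil and T and NK with IFNβ; at 12 h they gave 58 in interferon-stimulated, 6 in dendritic, 3 in cell cycle and T and NK, and for cytokines 4 without and 14 with IFNβ over time. Most of these matches are symbols of other genes. No named gene changed direction, but of 186 named values 57 no longer passed with the block without a variance trend and 40 without that trend, as did 141 of 1116 with a library left out. The 24 h table has no library values, and the 24 h libraries of the time tables, which are scaled separately, were not tested against each other, paired or unpaired; fits on counts were not run, and 2-group fits are the fits used. Depth is unknown and limits low genes.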

Other observations

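The genes of this paragraph were picked after their values had been seen, and their number is no test of a theme. At 12 h IFNβ lowered Mrc1 from 12592 ± 3224 to 2165 ± 1359 normalized counts (-2.71 ± 0.37), Ccl24 (-2.36 ± 0.40), Mgl2 (-1.55 ± 0.24), Cd163 (-2.45 ± 0.41), Pdcd1lg2 (-1.70 ± 0.28) and Ppargc1b (-1.73 ± 0.19), log2 differences ± SE. It raised the receptor genes Flt1, from 357 ± 91.8 to 3719.6 ± 414 (3.41 ± 0.21), Aplnr (4.36 ± 0.28), Eng (1.62 ± 0.16) and Nrp1 (1.58 ± 0.18). Asns, Nupr1 and Gtpbp2 were higher with IFNβ at 12 h and lower at 24 h than at 12 h under it: Asns differed by 1.21 ± 0.16 and then -1.40 ± 0.20, Nupr1 by 1.72 ± 0.17 and -1.27 ± 0.19, and Gtpbp2 by 1.42 ± 0.16 and -1.38 ± 0.18. Atf5 changed with time by -1.69 ± 0.21 without and -1.68 ± 0.19 with IFNβ. Nfkbie (1.30 ± 0.15 and -1.52 ± 0.18), Traf1 (1.90 ± 0.17 and -1.53 ± 0.20) and Ptgs2 (1.38 ± 0.24 and -2.46 ± 0.24) rose and then fell under IFNβ as Asns did. Ptgs2 also fell with time without IFNβ (-1.53 ± 0.30), and the difference between arms did not pass (limma interaction, adjusted p = 0.148). The deposited p-values imply 3099, 1345 and 1353 genes under an adjusted p of 0.05 at any fold for IFNβ at 12 h, time without IFNβ and time with it.

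Of the tests that follow, the bound on shared noise was set before its value was computed; the tests of the 24 h scale, of a scaling shift and of dendritic cells were chosen after the values they use had been seen. Of 1388 genes changed by IFNβ at 12 h, 253 were also called with time under IFNβ, and 204 of these moved the opposite way. Noise of the shared 12 h libraries came to 2.85% of the covariance (upper bootstrap bound over genes 3.74%), under the tenth set in advance. Both lists hold only genes past a fold limit and with small p-values. That selection enlarges the covariance and lowers the spread taken as noise, so the share cannot exclude such noise. A single scaling shift would move all genes one way, whereas 78.7% of the genes lower at 12 h rose and 81.7% of those higher fell. Without IFNβ, 49 of the 77 genes lower at 12 h that are also in the table of time in controls rose with time (63.6%, where 76.4% of that whole table rose), Fabp4 by 2.37 ± 0.29 and Mmp12 by 2.23 against 1.89 and 2.21 with IFNβ, so a rise in both arms need not be a return. What causes the opposite moves was not tested.

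The 24 h values may be log2 values under a heading of fold change: 4 of 5 lie outside the allowed range when read as linear and 0 when read as log2. The range assumes that a gene absent from a time table changed by less than 1 on the log2 scale.

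At 12 h 6 of 13 members of the class II list were lower with IFNβ. The 2 that were higher were the co-stimulatory genes Cd86 and Cd40, which do not encode class II molecules. Of 14 dendritic cell markers 4 were lower. The directions of both whole lists did not differ from the table's split (exact binomial test, adjusted p = 0.155 and 0.202). Fewer dendritic cells in the IFNβ libraries could produce falls in class II and dendritic cell genes. The cells were sorted as monocytes, and how many dendritic cells remained is not given in the sources used here. Cd209a fell by more than H2-Ab1, a difference of -2.70 ± 0.57 (log2, SE), and Xcr1 rose. Unequal falls neither need nor exclude a loss of such cells, since other cells also express H2-Ab1, so loss and lower transcription cannot be told apart.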
